A study of Mus musculus with 2 samples.

How the data were processed

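Chromatin from the facial prominences of B6NCrl mouse embryos at 11.5 days was immunoprecipitated with an antibody to H3K9ac and sequenced, per the labels, in 2 biological replicates. These were pools of 109 and 88 embryos of both sexes. The labels number the replicates and give each its own tissue sample. They also name a possible control experiment, which is not analysed here. The authors deposited 4 peak lists in the narrowPeak layout on the mm10 assembly: one per replicate, one made from both replicates' alignments together, and the replicated set, made from both replicates' lists and the pooled list, per the deposited file descriptions. All 28208 peaks of the replicated set were found in the pooled list with the same coordinates. The aligner, the peak caller and its settings are not given in the sources used here. The deposited descriptions list 2 further input files of unstated kind for replicate 1 and 1 for replicate 2, which both share, so the background of the 2 lists may not be the same.

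Each peak carries a fold enrichment given by the authors, a ratio whose background is not stated, and the authors' −log10 p-value and −log10 q-value, per the narrowPeak layout of the deposited files. These were used to describe, rank or filter peaks within a list. Enrichment and −log10 p were also set side by side between the replicates, by rank correlation and at named promoters, where a difference in level can come from the background. The lowest ratio in any list was 1.68 and the lowest −log10 p 2.05. The lowest −log10 q was 0.262 in replicate 1, 0.0152 in replicate 2, 0.106 in the pooled list and 0.108 in the replicated set, so the lists hold weak peaks, and 65.5% of replicated peaks had a q-value of 1e-05 or lower. The lists hold no read counts, so the depth behind each peak is unknown, and intervals given for shares of genes or peaks cover counting error only. Median peak widths were 315 bp in replicate 1, 466 bp in replicate 2, 472 bp in the pooled list and 663 bp in the replicated set, and the lists covered 30.4, 20.4, 26.0 and 24.1 Mb.

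Genes were those of GENCODE M21 on the GRCm38 assembly, of which mm10 is another name, and sequence was that of GRCm38.p6. No peak and no gene ended past a chromosome end. Analyses used chromosomes 1 to 19, X and Y and 21938 protein-coding genes, with every annotated TSS of each. A gene was called marked with at least 1 bp of a peak within 1 kb of any of its TSSs. Breadth was the length covered by peaks within 5 kb either side of the best covered TSS, and wide domains were the top 5% of marked genes. Distal peaks lay over 5 kb from every protein-coding TSS and were assigned to the nearest within 100 kb. Each peak was placed as promoter, else exon, else intron, else intergenic. Chance levels came from 100 circular shifts of the peaks along each chromosome.

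The gene lists were fixed before the data were examined, as were the tests, the thresholds and the other settings to be tried. There were 18 lists: facial mesenchyme and neural crest, pharyngeal arch patterning, facial ectoderm and epithelium, facial signalling, orofacial cleft and craniofacial syndrome, Hox, myogenic progenitor, cartilage and bone, neural and sensory neuron, endothelial, erythroid, macrophage, hepatocyte, cardiomyocyte, germline, housekeeping, ribosomal protein and olfactory receptor. The last 2 were taken by gene symbol. All symbols were matched, and some genes stand in more than one list: 9 of the 33 facial mesenchyme genes and 16 of the 37 craniofacial syndrome genes are in another list. The rule for naming genes allowed any list member, the 20 genes with the most covered length, the 10 distal peaks with the highest enrichment and the 10 genes with the most distal peaks. Near-identical copies, such as the paired alpha-globin genes, olfactory receptors and some ribosomal protein loci, can lose or share reads in alignment, and their marking is uncertain.

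Promoter marking and wide domains of each list were compared with those of all other genes, or of all other marked genes, by two-sided Fisher's exact tests. Distal peaks per gene were compared with 10000 random lists of the same size drawn from marked genes, with a two-sided permutation p whose smallest value is 0.0002. Adjusted p-values follow Benjamini-Hochberg over the lists, with a threshold of 0.05. Hox genes of paralog groups 1 to 4 and 9 to 13 were compared by Fisher's exact test. Replicate lists were compared by overlap of at least 1 bp and by Spearman correlation of enrichment over replicated regions. With 1 group and 2 replicates no test across samples was possible, and the tests compare genes within this tissue.

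The other settings chosen then were the pooled list, each replicate's list alone, peaks with a q-value of 1e-05 or lower, peaks above the median enrichment, promoter windows of 500 bp and 2 kb, an overlap of 200 bp, genes matched on promoter CpG count (10 bins, 1001 bp around the gene's 5' end), a breadth window of 10 kb, the top 10%, a distal limit of 1 kb, an assignment limit of 50 kb, an overlap of 50% of the peak, equal list lengths, and 2 other measures of strength. Added after seeing the data were basic protein-coding transcripts only, replicated peaks found in both replicates' lists, genes with no neighbouring TSS within 10 kb (with the widest 5% drawn anew among them), breadth matched on CpG count, random lists matched on territory length, distal peaks away from noncoding TSSs, and the exclusion of olfactory receptor genes.

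The scripts used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9. They were tested on simulated data for 21938 genes. Lists planted at 95% marked against 63% were called in 96.5% of cases, lists planted at 13% in 98%, and unchanged lists in 2%. Lists planted at a mean of 2 distal peaks against 0.35 were called in 86.7% of cases and unchanged lists in 0%. In the matched tests, planted lists were called in 98.9% of cases for means and 100% for marking, and lists that differed in the matched property alone in 0% and 1.25%. Interval functions gave the same values as a direct count in 1577 and 534 cases, with 0 that differed.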

Results

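H3K9ac, an acetylated lysine of histone H3 found at active promoters and at a part of active enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the facial prominences of B6NCrl mouse embryos. The facial prominences are swellings of mesenchyme, largely derived from the neural crest, under an ectodermal cover, and they grow and fuse to form the face. Tissue was collected at 11.5 days of embryonic development from embryos of both sexes. The series held 1 group of 2 biological replicates, a pool of 109 embryos for replicate 1 and a pool of 88 embryos for replicate 2. With no second condition, the comparisons were between the replicates and between sets of genes within the tissue. The deposited lists held 53981 peaks for replicate 1, 30719 for replicate 2, 36635 for both replicates pooled and 28208 for the replicated set, which is the list meant below unless another is named. The lists carry no read counts, so the sequencing depth is unknown, and a gene without a peak is a gene absent from a list, not a gene shown to lack the mark. Coordinates are those of the mm10 assembly.

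The first comparison was between the replicates. Promoter peaks, defined as peaks within 1 kb of a transcription start site (TSS), were found at 14443 of 21938 protein-coding genes in replicate 1 and at 13570 in replicate 2, and 13490 genes had one in both (63.8% ± 2.81 of genes per replicate, SD, n = 2). Among the genes of the facial mesenchyme and neural crest list, all 33 were marked in both replicates. The muscle regulators Myod1 and Myog and the macrophage genes Spi1, Cx3cr1, Aif1, Fcer1g and Laptm5 had a promoter peak in replicate 1 and none in replicate 2 or in the replicated set. Enrichment was 40.4-fold in replicate 1 and 34.0-fold in replicate 2 at the cytoskeletal gene Actb, and 30.8-fold and 23.5-fold at the homeobox gene Prrx1. The gap was wider at Bahcc1 (42.1-fold and 19.9-fold), Zeb2 (28.2-fold and 15.1-fold), Polr1c (26.2-fold and 9.34-fold) and Foxc2 (19.3-fold and 8.17-fold). These genes were chosen after their values were seen.

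By position, 46.1% of replicate 1 peaks were overlapped by at least 1 bp by a replicate 2 peak, and 88.1% of replicate 2 peaks were overlapped by replicate 1. Circular shifts of the other list gave means of 1.35% and 2.36%, and the highest of 100 shifts gave 1.57% and 2.68%. Replicate 1 had 1.76 peaks for each peak of replicate 2, and with the strongest peaks taken in equal number from both lists the overlaps were 72.5% and 81.4%. Across 23613 replicated regions that both lists overlapped, the Spearman correlation of enrichment was 0.854, a description across regions, which are not independent replicates. These regions were 83.7% of the replicated set on the assembled chromosomes, with a median enrichment of 7.54 against 3.499 for the remaining replicated peaks.

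The second comparison asked where in the genome the mark lay. Promoters held 18757 replicated peaks (66.5%), against a mean of 5.21% and a maximum of 5.66% in 100 circular shifts, a 12.8-fold excess. Among the 20 genes with the most covered length around a TSS, the highest promoter enrichments were 48.3-fold at Skida1, 40.8-fold at Tnrc18, 39.4-fold at Bahcc1 and 38.6-fold at the RNA-binding protein gene Mex3a. Exons away from promoters held 4.23% of peaks (6.15% by chance), introns 11.8% (30.2% by chance) and intergenic sequence 17.5% (58.5% by chance). Each peak was placed in 1 class, promoters first, so the promoter excess lowers all the other shares. These shares therefore do not show whether peaks outside promoters avoid exons or introns. Promoter peaks had a median width of 869 bp and a median enrichment of 9.06, and peaks over 5 kb from every protein-coding TSS had medians of 398 bp and 4.09. The promoter share was 44.05% in replicate 1 and 66.3% in replicate 2 (55.2% ± 15.7, SD, n = 2), so its exact level rested on the list used. In all, 13785 of 21938 protein-coding genes (62.8%, exact binomial 95% interval 62.2 to 63.5%) had a promoter peak. The interval covers counting error only.

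The third comparison set genes of the face beside genes of other tissues. All 33 facial mesenchyme and neural crest genes had a promoter peak (100% against 62.8% of the other genes). They included Prrx1 (30.4-fold enrichment), Alx4 (29.2-fold), Twist1 (23.4-fold) and Pdgfra, which encodes a receptor of neural crest mesenchyme (22.7-fold). Of the pharyngeal arch patterning genes 16 of 17 were marked, including Dlx1, Dlx2, Dlx3, Dlx4, Dlx5, Dlx6, Hand2 and Gsc. The exception was Edn1, which encodes the signal endothelin. Of the facial signalling genes 27 of 28 were marked, with Ptch1, a receptor of Hedgehog signals, at 29.5-fold, Fgfr2 at 25.3-fold and Spry2 at 25.4-fold. The signal gene Shh had a promoter peak in replicate 2's list (3.34-fold) and none in the replicated set. Of the genes of orofacial clefts and craniofacial syndromes 35 of 37 were marked, with Mn1 at 32.2-fold and the chromatin remodeller gene Chd7 at 27.0-fold. The epithelial regulators Irf6 and Grhl3 were unmarked, and Irf6 had a weak peak in replicate 1's list (2.91-fold). At the other end, Alb, Afp and Ttr, abundant transcripts of liver, were unmarked with 14 of the 16 hepatocyte genes. None of the 13 macrophage genes was marked (exact binomial 95% interval 0 to 24.7%).

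**Figure D1:**
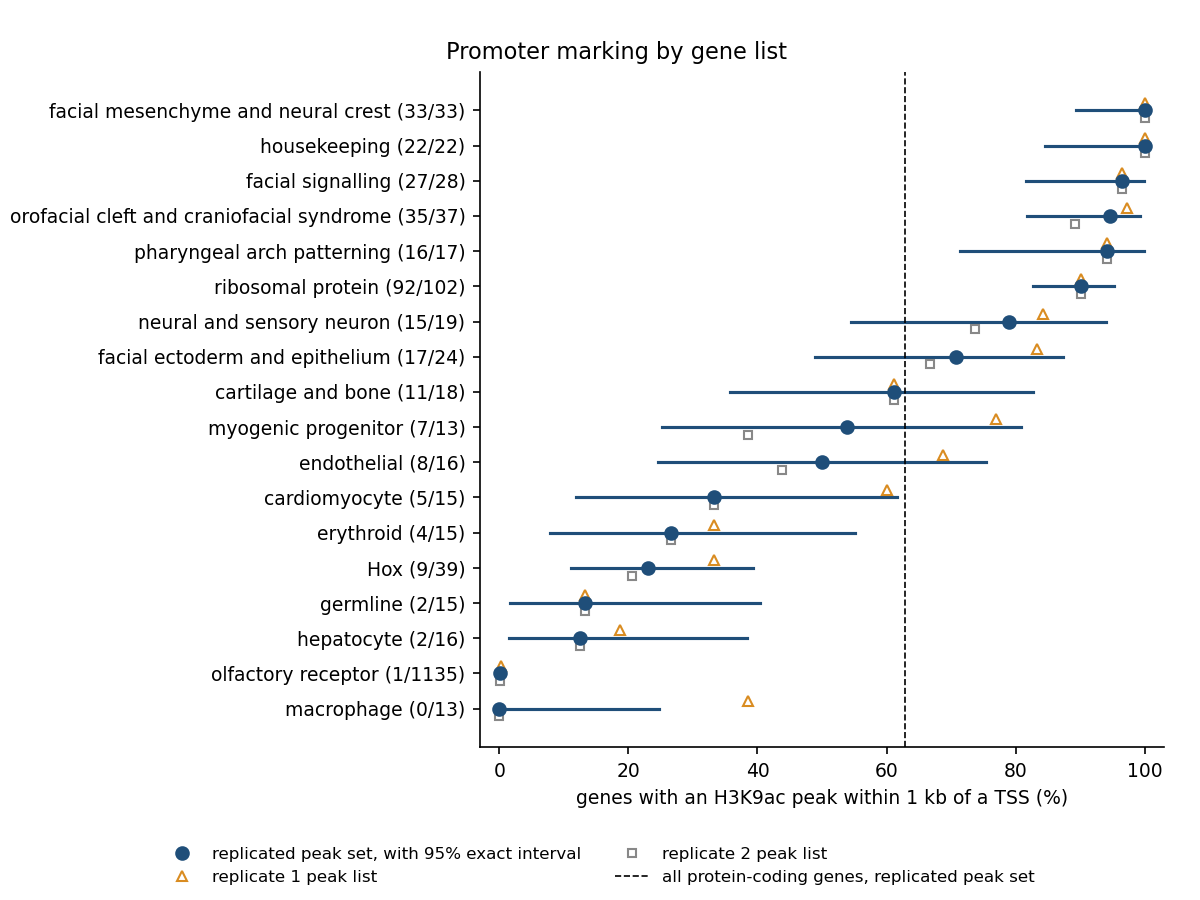
Share of the genes of each list with an H3K9ac peak within 1 kb of a TSS, in percent, with the number marked and the list size beside each name. Filled circles with bars give the replicated set with its exact 95% interval, triangles replicate 1, squares replicate 2, and the dashed line all protein-coding genes (62.8%); the facial mesenchyme list lies at 100% in all 3, and the macrophage list at 0% in the replicated set and 38.5% in replicate 1.

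Housekeeping genes were marked at 22 of 22 and ribosomal protein genes at 92 of 102. The facial ectoderm and epithelium list had 17 of 24 marked, with peaks at the epithelial genes Cdh1 (4.77-fold), Epcam (6.25-fold) and Grhl2 (10.1-fold) and none at Trp63, Krt5, Krt14, Krt19, Rab25, Irf6 and Grhl3. The neural and sensory neuron list had 15 of 19 marked, the cartilage and bone list 11 of 18, the endothelial list 8 of 16 and the myogenic progenitor list 7 of 13. In the cartilage and bone list, peaks were found at Sox5, Sox6 (18.1-fold), Sox9 (15.5-fold), Col2a1 (11.3-fold), Col9a1, Col11a1, Acan and Comp and at the bone genes Runx2 (14.9-fold), Sp7 (5.76-fold) and Alpl (4.29-fold). The cartilage genes Matn1, Matn4, Col10a1 and Ihh and the bone matrix genes Ibsp, Bglap and Spp1 were unmarked. The cardiomyocyte list had 5 of 15 marked, with the atrial and fetal myosin light chain gene Myl4 at 33.1-fold and the other marked genes at 3.49-fold to 9.21-fold. Marking was not tested for the TSSs of neighbouring genes, so a promoter peak such as that of Myl4 may belong to a neighbour. The erythroid list had 4 of 15 marked, with the erythroid regulator Klf1 at 13.1-fold and all 7 globin genes unmarked. The germline list had 2 of 15 marked, Dazl and Gdf9, and the olfactory receptor list 1 of 1135, Olfr94.

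In two-sided Fisher's exact tests against all other protein-coding genes, adjusted by Benjamini-Hochberg over 18 lists, 6 lists were marked more often: facial mesenchyme (adjusted p = 2.43e-06), facial signalling (0.00011), craniofacial syndrome (3.21e-05), arch patterning (0.00855), housekeeping (0.000119) and ribosomal protein genes (3.91e-09). Marked less often were the Hox (3.61e-06), macrophage (9.23e-06), hepatocyte (0.00011), germline (0.000208), erythroid (0.0087), cardiomyocyte (0.04) and olfactory receptor lists. The other 5 lists did not pass. Against genes matched on promoter CpG content, the calls that held were facial mesenchyme genes (100% against 84.9%, adjusted p = 0.0072, permutation) among the lists marked more often, and the Hox (23.1% against 85.0%, adjusted p = 0.0012), germline and olfactory receptor lists among those marked less often. The other 9 calls ended there, the erythroid difference changed sign, and the cardiomyocyte and macrophage calls also ended in replicate 1's own list, where 9 of 15 and 5 of 13 genes were marked. In the matched test, housekeeping (100%) and macrophage genes (0%) already stood at the limit of the measure (adjusted permutation p = 0.105 for both). For arch genes the upper matched limit was 100%. No more extreme share could have passed in these lists, so the test could not decide whether CpG content explains their calls. The CpG count was taken at the gene's 5' end, which for some genes, such as Runx2, is not the best covered TSS. The facial mesenchyme call thus held against CpG count at that end, and CpG content at each marked TSS was not tested.

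The fourth comparison was of the breadth of the mark. Around the best covered TSS of a marked gene, peaks covered a median of 1490 bp of the surrounding 10001 bp, and the widest 5% of marked genes (689 genes) had at least 3496 bp. Facial mesenchyme genes had a median of 5142 bp, and 27 of 33 were among the widest. They were led by Six2 (8960 bp in the replicated set; 8544 ± 1230 bp in the replicates' lists, SD, n = 2), Msx1 (7743 bp; 7684 ± 864 bp), Lhx8 (7711 bp; 7236.5 ± 1136 bp), Pdgfra (7582 bp), Six1 (7227 bp) and Tfap2a (7177 bp). Of the arch patterning genes 10 of 16 were among the widest, with Six1, Dlx1 (6932 bp), Dlx6 (6761 bp) and Pou3f3 (6692 bp) ahead, and Hand1 had 246 bp. Of the craniofacial syndrome genes 15 of 35 were, including Meis2 (9853 bp), Mn1 (7186 bp) and Satb2 (7115 bp). Of the facial signalling genes 10 of 27 were, including Wnt5a (6868 bp), Ptch1 (6415 bp) and Lef1 (6322 bp). In the facial ectoderm list the genes among the widest were the homeobox genes Pitx1 (7250 bp) and Pitx2 (4154 bp), and the epithelial genes Cdh1 and Epcam had 916 bp and 678 bp.

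**Figure D2:**
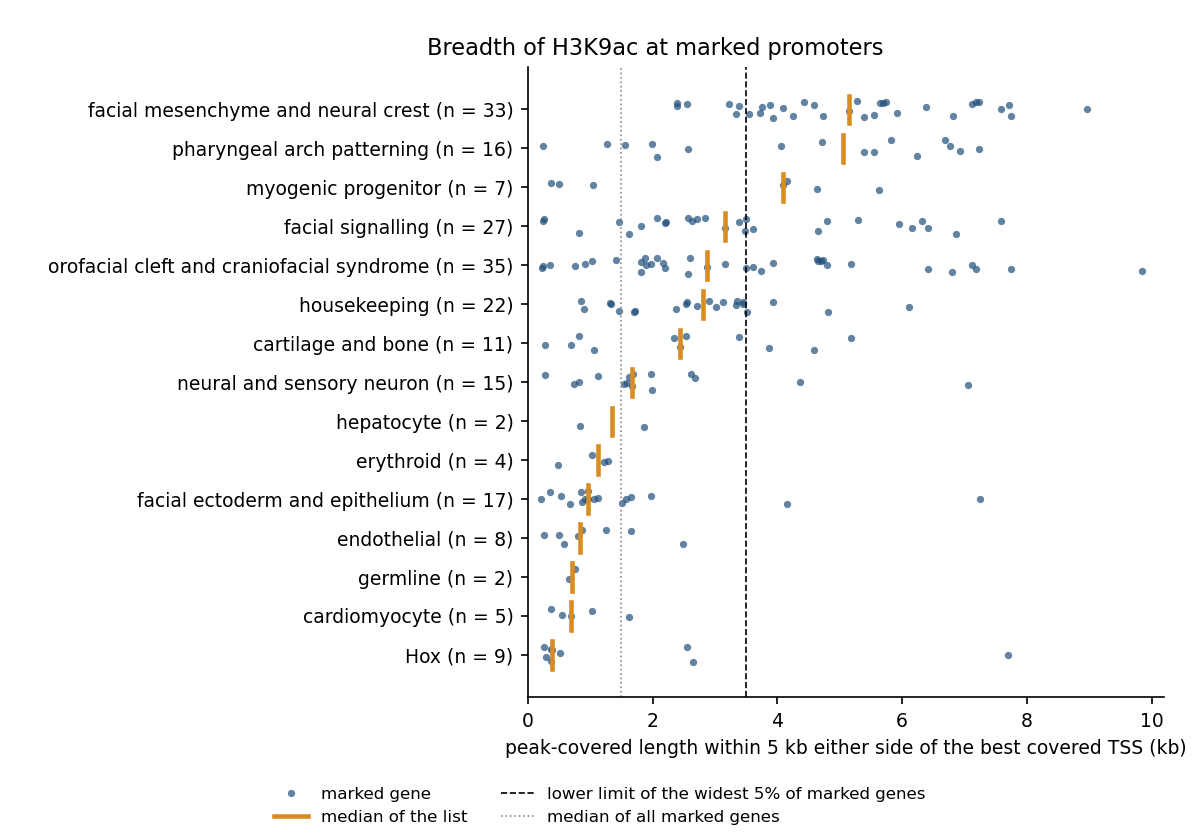
Peak-covered length in kb within 5 kb either side of the best covered TSS, 1 point per marked gene of each list (the ribosomal protein and olfactory receptor lists are left out), in the replicated set. Orange bars are list medians, the dashed line is the lower limit of the widest 5% (3496 bp) and the dotted line the median of all marked genes (1490 bp); facial mesenchyme and arch genes have medians of 5142 and 5046.5 bp.

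The 20 protein-coding genes with the most covered length were Tnrc18 (9880 bp), Meis2, Nr2f2 (9065 bp), Six2, Mex3a (8955 bp), Tbx2 (8823 bp), Skida1, Zmynd8, Msi1, Irx5 (8463 bp), Bahcc1, Smad7, Gm42742, Prrt2, Tbx3 (8142 bp), Prdm16 (8041 bp), Bcl11a, Ebf3, Msx1 and Lhx8. Several encode transcription factors of the developing embryo, such as the T-box genes Tbx2 and Tbx3 and the homeobox genes Meis2, Six2, Irx5, Msx1 and Lhx8. The best covered window of Meis2 was chromosome 2, 116060047 to 116070047, that of Six2 chromosome 17, 85683254 to 85693254, and that of Msx1 chromosome 5, 37819582 to 37829582. No other protein-coding TSS lay in these 3 windows. The windows of Gm42742 and Prrt2 overlapped almost fully, and each also held TSSs of Maz, Pagr1a and Pagr1b.

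Fisher's exact tests among the 13785 marked genes called 8 lists higher: facial mesenchyme (81.8% against 4.81% of the other marked genes, adjusted p = 6.4e-29), arch patterning (62.5%, 3.15e-09), craniofacial syndrome (42.9%, 2.83e-10), facial signalling (37.0%, 1.51e-06), myogenic progenitor (4 of 7 genes, 0.000652), cartilage and bone (3 of 11, 0.0369), housekeeping (4 of 22, 0.0469) and ribosomal protein genes (11 of 92, 0.0171). The 4 myogenic genes were Lhx2, Pax7, Pitx2 and Tbx1, which are also used outside muscle. Myf6 (3.82-fold), Des (3.82-fold) and Msc (6.83-fold) were marked but not among the widest, and Myod1, Myf5 and Myog had no promoter peak. In a test chosen after seeing the data, the widest 5% were drawn anew (383 genes) among 7666 marked genes with no other protein-coding TSS within 10 kb. They held 26 of 30 facial mesenchyme genes, and the housekeeping (0 of 8) and ribosomal protein (0 of 27) calls ended, in lists too small to show a lower share. In replicate 2's list alone the cartilage and bone, myogenic, housekeeping and ribosomal protein calls ended (adjusted p = 0.0515 to 0.0534, Fisher's exact test), with differences of 22.3, 35.0, 13.2 and 5.91 percentage points against 22.3, 52.2, 13.2 and 7.01 in the replicated set.

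The fifth comparison counted peaks away from promoters. Arch patterning genes with a promoter peak had a mean of 2.75 distal peaks each, that is peaks over 5 kb from every protein-coding TSS and nearest to that gene within 100 kb, against 0.344 for all marked genes. The cardiac and arch transcription factor gene Mef2c had 10, Hand2 and Pou3f3 had 7 each, and Barx1 had 4, and 12 of 16 genes had at least 1. Facial mesenchyme genes had a mean of 1.94, and 24 of 33 had at least 1. Pax7 had 7, Prrx2 had 5, and Alx4, Twist1, Tfap2a, Foxc1, Msx2, Barx1 and Snai1 had 4 each. Craniofacial syndrome genes had a mean of 1.31, with at least 1 distal peak at 12 of 35 genes and the most at Mn1 (11), Fgfr1 (7), Chd7 (5) and Meis2 (5). Facial signalling genes had a mean of 1.26, with at least 1 at 14 of 27 genes and the most at Fgfr1, and housekeeping genes 0.50, with at least 1 at 5 of 22. The genes with the most distal peaks lay outside the lists: Gse1 had 31, Cstad 21, 1700001O22Rik 18, Prdm16 and Bahcc1 17 each, Dnm3 16, Sh3pxd2a 15, and Ahdc1, Mrpl23 and Zfp423 14 each. Over the same genes, replicate 1's list gave higher means: 4.63 for arch, 4.52 for facial mesenchyme, 3.49 for craniofacial syndrome and 3.89 for signalling genes, with 20 distal peaks at Mef2c and 18 at Pax7. Replicate 2's list gave 3.31, 2.24, 1.49 and 1.11, with 10 at Mef2c and 5 at Pax7. Counts outside the gene lists also moved: replicates 1 and 2 gave 78 and 37 at Gse1, 36 and 27 at Cstad and 45 and 12 at Prdm16. Cstad (start at 30595040), 1700001O22Rik (30794769) and the list gene Prrx2 (30834972) lie near one another on chromosome 2. Assignment to the nearest TSS can divide the peaks of such a region among its genes.

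In all there were 6383 distal peaks (22.6% of the replicated set), 65.0% of them intergenic. The strongest was a peak of 1988 bp with 47.8-fold enrichment at chromosome 7, 73556644 to 73558631. It lay within 1 kb of a TSS of the noncoding gene 1810026B05Rik and 14.8 kb from the TSS of the chromatin remodeller gene Chd2. The next, at chromosome 10, 122984843 to 122987105, had 42.0-fold enrichment and lay at the microRNA gene Mirlet7i. The one after, at chromosome 14, 115040170 to 115043022, had 34.6-fold enrichment and lay at Mir17hg, the host gene of a microRNA cluster. Of the 10 strongest distal peaks, 9 were within 1 kb of a TSS of a gene annotated as noncoding or of a noncoding transcript. Of all 6383 distal peaks 1000 (15.7%) were, against a mean of 3.16% in 100 circular shifts. With all such distal peaks left out, a choice made after seeing the data, the arch mean was 1.63 and the facial mesenchyme mean 1.85 (adjusted permutation p = 0.0272 and 0.0034). Against 10000 random lists of marked genes, 4 lists had more distal peaks: arch patterning and facial mesenchyme (adjusted permutation p = 0.0017 for both, from the smallest p the draws can give), craniofacial syndrome (0.0181) and facial signalling genes (0.0323). When random lists were matched on the length of sequence nearest to each gene, a choice made after seeing the data, the arch (adjusted permutation p = 0.0051) and facial mesenchyme (0.0034) calls held and the craniofacial syndrome (0.0771) and signalling (0.149) calls ended. Those 2 calls also ended with peaks of a q-value of 1e-05 or lower and with peaks above the median enrichment, and the signalling call ended in replicate 2's list. With those stricter peaks the arch and facial mesenchyme calls held, with the differences from random lists down from 2.40 and 1.60 peaks per gene to 1.21 and 0.601, and to 0.579 and 0.259.

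The sixth comparison was along the Hox clusters, whose genes are ordered by the body level at which they act. Marked promoters were at the anterior end: 8 of 12 genes of paralog groups 1 to 4, 1 of 11 genes of groups 5 to 8 and none of 16 genes of groups 9 to 13. Hoxa2, which patterns the second pharyngeal arch and the hindbrain, had 7706 bp covered around its TSS (6528.5 ± 1560 bp in the replicates' lists, SD, n = 2) and a promoter enrichment of 8.10. Hoxb2 had 2650 bp (7.80-fold) and Hoxa1 2547 bp (5.54-fold). The windows of Hoxa1 and Hoxa2 overlapped, so part of this length was counted for both genes. The peak next to the Hoxa1 TSS was 428 bp wide. Hoxa4, Hoxb3, Hoxb4, Hoxd1, Hoxd3 and Hoxd8 had peaks with 260 to 519 bp covered and enrichments of 2.45 to 5.05. Peaks covered 8.95% of the Hoxa cluster (chromosome 6, 52155590 to 52260880), 2.69% of Hoxb (chromosome 11, 96194316 to 96368256), 2.15% of Hoxd (chromosome 2, 74668310 to 74765142) and none of Hoxc (chromosome 15, 102921103 to 103036852). The covered length differed between replicates 1 and 2: 10621 and 6632 bp in Hoxa, 6337 and 2629 bp in Hoxb, 3472 and 932 bp in Hoxd, and 220 and 0 bp in Hoxc.

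**Figure D3:**
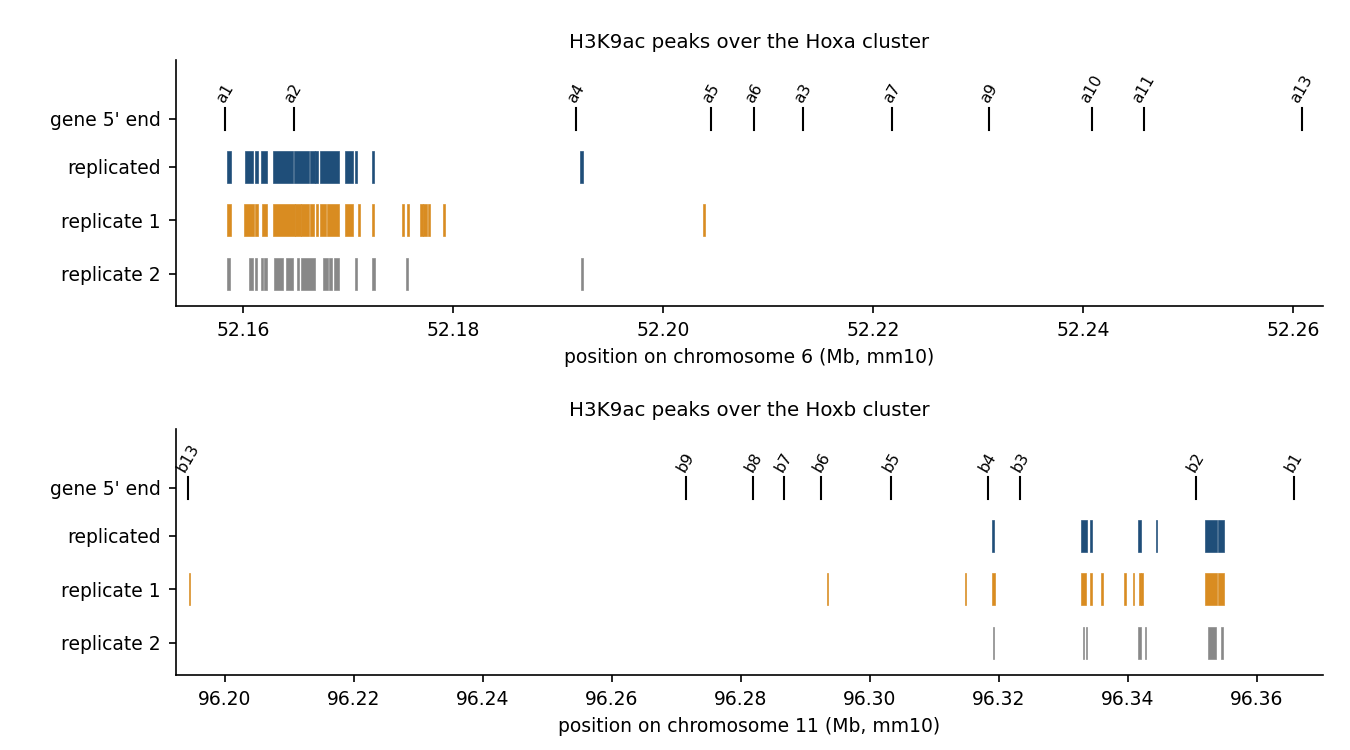
H3K9ac peaks (bars, to scale) of the replicated set and of each replicate over the Hoxa and Hoxb clusters, against position in Mb on the mm10 assembly; ticks mark the annotated 5' end of each gene, which for some genes is that of a long transcript. Replicated peaks cover 9424 bp of Hoxa, most of it next to Hoxa1 and Hoxa2, and 4680 bp of Hoxb, with none at groups 5 to 13 in either cluster.

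The difference between groups 1 to 4 and groups 9 to 13 passed Fisher's exact test in the replicated set (two-sided p = 0.000159), in replicate 1 (7 of 12 against 2 of 16, p = 0.0166) and in replicate 2 (7 of 12 against 0 of 16, p = 0.000669). The test treats the genes as independent, but they lie side by side in clusters, so these p-values may be too small. The difference of 66.7 percentage points fell to 33.3 with peaks of a q-value of 1e-05 or lower, where it still passed (p = 0.0242, Fisher's exact test). Among replicated peaks above the median enrichment it was 16.7 and did not pass (p = 0.175, Fisher's exact test).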

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

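Of the 28208 peaks in the replicated set, 5 lay on unlocalised or unplaced scaffolds. They stand out as a signal in sequence that none of the comparisons used. Whether they reflect placed sequence missing from the assembled chromosomes was not tested.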

How the results depend on the processing

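Tests on basic transcripts, on replicated peaks found in both replicates' lists, on genes without neighbours, on breadth matched on CpG count, on territory-matched lists, without noncoding TSSs and without olfactory receptors were chosen only after the results were seen; the others were planned. Of 669 alternative values, 579 kept their direction and side of the threshold or, for values without a test, moved less than a set limit. Tests that passed neither in the main setting nor in the alternative are among them. For counts the limit was a fixed factor and not a spread: 3 and 5 lists with more distal peaks counted as unchanged from 4. The facial mesenchyme list kept its direction and side of the threshold in all 34 alternatives of marking, breadth and distal peaks. The arch list did so in 33 of 34, the exception being marking matched on CpG content. The size of their distal differences moved more: from 1.60 for facial mesenchyme and 2.40 for arch genes to 0.601 and 1.21 at a q-value of 1e-05 or lower, 0.259 and 0.579 above the median enrichment, 2.49 and 3.19 in the pooled list and 3.55 and 3.77 from 1 kb on, and for arch genes to 1.53 with a limit of 50 kb and 1.33 without noncoding TSSs. The number of marked genes ranged from 11667 to 14443. Depth could not be varied, since the lists hold no reads, so what deeper sequencing would add is not known. Values below are differences, list minus background, in percentage points for marking and wide domains and in peaks per gene for distal peaks. Where peaks or genes were left out there was less to count; otherwise the cause was not tested.

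With the pooled list the marking difference was -17.7 for cardiomyocyte genes (call lost) and 12.6 for myogenic genes (sign changed), and ribosomal breadth was 5.91 (call lost). Distal values changed sign for endothelial (0.332) and germline genes (-0.048), and neural genes passed (1.90).

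With a q-value of 1e-05 or lower, ectoderm (-12.7) and neural marking (-0.589) changed sign, 2 lists had more distal peaks, with signalling at 0.123 and craniofacial syndrome at 0.292 (calls lost), and the replicate overlaps were 72.5% and 97.9%. With peaks above the median enrichment the promoter share was 88.7% and the Hox difference 16.7 (call lost). Endothelial marking passed (-40.7), and ectoderm (-15.7) and neural marking (-16.4) changed sign. There 5 lists had more wide domains, with housekeeping 13.2, myogenic 15.0 and ribosomal 6.04 (calls lost), and 2 had more distal peaks, with craniofacial syndrome 0.195 (call lost) and cartilage -0.0627, signalling -0.0184 and germline -0.0642 (sign changed). Ectoderm marking also changed sign with a 500 bp window (-3.82) and an overlap of 200 bp (-0.0308).

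Matched on promoter CpG content, 1 list was marked more often and 3 less often. Calls were lost for cardiomyocyte (-21.4), signalling (8.61), hepatocyte (-22.2), housekeeping (12.8), macrophage (-25.6), craniofacial syndrome (8.29), arch (7.21) and ribosomal genes (5.52). For housekeeping, macrophage and arch genes no more extreme share could have passed, so their lost calls decide nothing. Signs changed for cartilage (2.94), erythroid (5.19) and ectoderm genes (-6.09). The matched share of wide domains lost the cartilage (22.7, adjusted permutation p = 0.0539) and housekeeping (14.0, 0.0540) calls, with differences no smaller than unmatched. In the matched mean covered length, cartilage (adjusted permutation p = 0.0251) and housekeeping genes (0.000567) passed.

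With distal peaks taken from 1 kb on, Hox (0.913), endothelial (0.0777) and germline (-0.055) values changed sign, and myogenic (2.46) and neural genes (1.99) passed. With a limit of 50 kb, Hox changed sign (0.0584) and neural genes passed (1.05). With basic transcripts, the housekeeping (13.2) and ribosomal (3.72) breadth calls were lost, distal Hox (0.162), endothelial (0.0359) and germline (-0.404) values changed sign, and neural genes passed (1.14). With replicated peaks in both replicates' lists, the housekeeping (8.65) and ribosomal (5.91) breadth calls and the signalling distal call (0.647) were lost. Without neighbouring genes and with the widest 5% drawn anew, breadth was -4.997 for Hox (0 of 1 gene), -5.001 for housekeeping (0 of 8) and -5.01 for ribosomal genes (0 of 27). At these sizes a count of 0 says nothing on the direction. Matched on territory, 2 lists had more distal peaks, signalling (0.711) and craniofacial syndrome (0.820) calls were lost, and Hox (0.214) and ribosomal values (0.0132) changed sign. Without noncoding TSSs, the germline value was -0.2985 (sign changed).

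An overlap of 50% of the peak gave 40.1% and 83.9% of replicate 1 and 2 peaks, and equal numbers of peaks gave 72.5% and 81.4%. The Spearman correlation was 0.880 with −log10 p and 0.832 with the mean over peaks.

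Leaving out replicate 1 and then replicate 2 gave these pairs. The promoter share was 66.3% and 44.05%. Marking was -28.5 and -5.84 for cardiomyocyte, -18.1 and 2.92 for endothelial, -61.9 and -27.4 for macrophage and -23.4 and 11.1 for myogenic genes. There were 4 and 8 lists with more wide domains, with cartilage at 22.3 in both, housekeeping 13.2 and 22.3, myogenic 35.0 in both and ribosomal 5.91 and 9.19. Distal values were 2.95 and 3.52 for arch, 1.88 and 3.40 for facial mesenchyme and 1.21 and 2.28 for craniofacial syndrome genes, with every one of these past the threshold. They were 0.00624 and -0.786 for Hox, -0.0827 and 1.53 for endothelial, 0.821 and 2.78 for signalling, 0.136 and -0.0889 for germline and 0.183 and -0.479 for housekeeping genes.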

Other observations

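The tests below on splitting, on genes without neighbours, on CpG-matched breadth, on territory-matched lists and without noncoding TSSs were chosen only after the result was seen, as was the choice of transcription factor families described. No family was tested. Of all protein-coding genes 62.8% had a promoter peak, and several of the families have only 2 or 3 members. Full marking of such a small family says little. Every member had a promoter peak in the Alx, Barx, Dlx, Eya, Hand, Meis, Msx, Pitx, Prrx, Runx, Twist and Zic families, and at Six1, Six2, Six3, Six4, Six5 and Six6. Other families were marked in part, with 16 of 19 Sox, 33 of 44 Fox, 9 of 13 Tbx, 7 of 8 Lhx, 5 of 6 Irx, 4 of 6 Gata, 3 of 5 Tfap2, 9 of 15 Pou, 7 of 14 Nkx and 4 of 11 Dmrt genes. Of the Pax genes Pax2, Pax3, Pax6, Pax7 and Pax9 were marked and Pax1, Pax4, Pax5 and Pax8 were not. Tbx5, a gene of the heart and forelimb, had a promoter peak in replicate 1's list alone (3.48-fold). None of the 3 Cdx genes, which act in the posterior embryo, was marked in the replicated set, and Cdx1 had a peak in replicate 2's list (4.43-fold).

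On the X chromosome 429 of 948 protein-coding genes (45.3%) had a promoter peak, against 64.2% of 20807 autosomal genes, and on the Y chromosome 3 of 183 had one. The pools held both sexes, and the difference was not tested. Replicated peaks that only replicate 1's list overlapped numbered 3939, those that only replicate 2's overlapped 502, and 149 were overlapped by neither list.

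Replicate 1 had 1.76 peaks for each peak of replicate 2. Its 29107 peaks without a replicate 2 overlap were narrower (median 229 bp against 746 bp) and weaker (median −log10 p 4.09 against 16.8), and 20.2% touched a promoter window, against at most 4.999% in 100 circular shifts. This argues against background spread evenly along the chromosomes as the only source. The shifts cannot test background that itself gathers at promoters, and the control was not analysed. Of the 29107 peaks 19.2% were above the median −log10 p of replicate 1's list, between the shares set for and against a lower detection limit, so greater depth or a different control may contribute. Splitting of wide domains within replicate 2's peaks would raise the number of shared peaks in replicate 1. There were 0.919 shared replicate 1 peaks per shared replicate 2 peak (95% interval 0.915 to 0.924, chromosomes resampled). This argues against splitting within the shared peaks as the source of the excess. Fragments lying beside replicate 2's peaks count as unshared, so the ratio cannot test them. No biological explanation was tested.

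The wide domains at facial mesenchyme genes were set against 2 technical explanations. Their mean of 5128 bp was above the highest of 10000 lists matched on promoter CpG count (2385 bp). That count covered 1001 bp at the gene's 5' end, which for some genes, such as Runx2, is not the best covered TSS. CpG count there could not account for the pattern, but CpG content over the whole breadth window was not tested. Of the facial mesenchyme genes with no neighbouring TSS within 10 kb, 86.7% were in the widest 5% drawn anew among such genes. Promoters of neighbouring protein-coding genes thus could not account for the whole pattern. Its biology remains a hypothesis, since no biological explanation was tested with 1 group and the pattern was found and tested on the same data.

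The distal peaks near arch and facial mesenchyme genes were also set against 2 technical explanations. The lower of the ratios to lists matched on territory length was 3.498. With distal peaks at noncoding TSSs left out, the lower of the ratios to random lists was 5.48. Neither explanation alone could account for the whole pattern, and the 2 were not tested together. That these peaks are enhancers of the nearest gene is a hypothesis that was not tested, and a peak may act on another gene.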
